A study of Phrynocephalus versicolor with 6 samples.

How the data were processed

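Dorsal skin of adult variegated toad-headed lizards (Phrynocephalus versicolor), a small agamid lizard of the Gobi Desert, was profiled by RNA sequencing. The labels place 3 individuals in the melanic population HSK (individuals 2, 7 and 19) and 3 in the non-melanic population GZ (individuals 35, 40 and 42), with 1 library per individual. Per the labels' protocols, the tissue was frozen in liquid nitrogen, total RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The label of GZ 42 adds that the second read of each pair is missing from its public raw data. Whether its counts came from single reads is not stated.

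Per the submitters' processing notes, CASAVA 2.19, RSEM, SAMtools 0.1.18, Picard and DESeq2 were used, with no role or order given. Per the series' design text, the reference was a transcriptome made from several tissues of a single female. The assembler, the aligner and their settings are not given in the sources used here. The deposited table of each library holds an expected count for each assembled cluster of transcripts, called a unigene here, and 251189 unigenes are listed. On average 7.63% of the expected counts the authors deposited were not whole, at a tolerance of 1e-06, so counts were rounded to whole numbers first. The FPKM values deposited beside the counts, which are scaled for unigene length and depth per the file headers, were not used in any test. The authors also deposited their own test of GZ against HSK. Per the file headers, it gives a signal per population, the authors' normalized mean read count, together with a log2 fold change, a p-value and an adjusted p-value. The log2 fold change the authors deposited is GZ over HSK, as its sign against the means showed in 99.5% of unigenes, and it is printed here as HSK over GZ. Other deposited values, per the file headers, are the length of each unigene and the expectation value of its best Swiss-Prot match, in a table that also names the best matches in NR and other databases and the GO terms. No genome came with the data, so no gene has coordinates. The deposited annotation gives KEGG orthologs but no pathways, so the KEGG pathways planned beside the GO terms were not tested.

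Gene names are those of the best Swiss-Prot match. A Swiss-Prot gene name was present for 23670 of the 77439 tested unigenes, which carried 12958 different names. Names come from similarity to proteins of other animals and do not show orthology. Several unigenes can share a name, and reads of near-identical copies, such as MHC and immunoglobulin genes, could be split between them, so values of single members of those families are uncertain.

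Counts were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test was used with TMM scaling and filterByExpr (minimum count 10, minimum total 15). Between 97.2% and 98.1% of each library's counts fell in the tested unigenes. The model held population alone, log2 fold changes are HSK over GZ, and a change was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic, an approximation, and 95% intervals from the t distribution with the fit's degrees of freedom. Means of CPM, counts scaled to the effective library size, are given with their SD over n = 3 libraries.

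The design, the test, the 29 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. A list symbol was matched to the Swiss-Prot gene name, and where several tested unigenes shared it, the one with the highest summed count stood for it. Some older or species-specific spellings, and 9 symbols matched through NR or other protein names, such as MLANA, CD8B and CSF1R, were added after the files were seen. In this way 433 of the 500 list symbols were measured. CSF1R, CRY1 and PCNA each stand in more than 1 list. Skin holds keratinocytes, fibroblasts, vessels, nerves and immune cells, so their markers belong in it, while skeletal muscle lies beneath it. Lists were tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry, which asks whether a list's members move 1 way on balance, were run beside it. Members were also adjusted over the list alone. A list score is the mean over members of the log2 CPM (prior count 1), centred per gene. GO terms with 10 to 500 tested unigenes were tested with a one-sided Fisher's exact test against the 28718 tested unigenes that have a GO term, adjusted over 1203 terms per direction.

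The genes named in the text follow a fixed rule. First, 14 pigment genes were to be named whatever their result, and other members of the melanin synthesis and melanocyte specification lists could be. Second came the 10 unigenes per direction with the largest log2 fold change among those past the adjusted threshold. These needed a Swiss-Prot gene name, a mean of at least 5 CPM and no overlap between the populations, and mobile elements and uncharacterized proteins were left out. Last came, for each list, up to 4 members with the smallest adjusted p that passed, or the 2 most abundant members where none did. Further genes are named as examples of a list or a term, and where they stand outside all of these the text says that they were chosen after their values were seen.

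The libraries held between 20337637 and 26536599 counts. The 95% intervals printed come from the edgeR fit and thus include the spread between individuals, and the 1 limit from counts alone, an exact binomial one, covers counting error only. The steps were tested on simulated data with the real means and library sizes, and with the real trend of spread over abundance. Single unigenes did not vary around that trend as real ones do, so the rates in the real data can differ. In the simulated data 200 unigenes were changed and 15 more, shifted by 1 on the log2 scale, formed a planted list. Changed unigenes that the filter removed count as not recovered. Of the 72203 simulated unigenes tested, edgeR recovered 2.99% of those changed by 1 on the log2 scale, 34.3% of those changed by 2 and 77.3% of those changed by 3. It made 2 false calls among the 71997 tested unigenes that were neither changed nor in the planted list. By these recovered shares, the power to call changes under 2 on the log2 scale was low in this design, with a biological coefficient of variation of 0.396. Camera called the planted list and 0 of 29 other lists. The term test was run apart from the simulated calls, on 100 unigenes of which a part was taken from 1 term and the others at random. It called that planted term, which the choice of unigenes all but ensured, and 5 of 1189 other terms. Other terms can share unigenes with the planted one, so the 5 gives no rate of false term calls. The simulated unigenes were drawn independently of each other. Members of real lists vary together, with an estimated correlation of 0.658 for basal keratinocytes. The 0 of 29 therefore gives no rate of false list calls in the real data.

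The alternative settings fixed beforehand were DESeq2 size factors and upper-quartile scaling in edgeR, no filter and a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, counts summed per gene name, a minimum absolute log2 fold change of 1, and leaving out each library in turn. For lists, the alternatives were an estimated correlation, fry and every unigene of a name, and for terms camera on each term. The list score of skeletal muscle as a covariate, and DESeq2 without single libraries, were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, matplotlib 3.10.9 and scipy 1.17.1.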

Results

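Dorsal skin of 6 adult variegated toad-headed lizards was compared, 3 from the melanic population HSK and 3 from the non-melanic population GZ, with 1 RNA library per individual. Libraries held between 20337637 and 26536599 counts over 251189 assembled transcript clusters, called unigenes here, of which 77439 passed the filter on low counts and were tested with edgeR. The comparison asks which transcripts differ in level between melanic and non-melanic skin. The first principal component carried 29.0% of the variance and placed the GZ libraries between -122.2 and -52.96 and the HSK libraries between 66.6 and 154. All log2 fold changes are HSK over GZ, and gene names are those of the best Swiss-Prot match. Mitochondrial transcripts took between 4.60% and 8.96% of the counts in GZ and between 3.39% and 8.91% in HSK.

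The genes of this paragraph were named by a fixed rule, the largest log2 fold changes per direction among called unigenes with a gene name and a mean of at least 5 CPM. IGLL5, an immunoglobulin light chain gene, rose from 5.98 ± 0.831 CPM in GZ to 560.2 ± 498 CPM in HSK (SD, n = 3; log2 fold change 6.55, SE 0.67, adjusted p = 0.0202). IGHE and IGHM, which encode immunoglobulin heavy chains, rose by 6.02 (SE 0.84, adjusted p = 0.0396) and 5.18 (SE 0.55, adjusted p = 0.0211) on the log2 scale. IGJ, whose product joins secreted antibodies, rose by 5.81 (SE 0.60), POU2AF1, a coactivator of B cells, by 6.52 (SE 0.89), and PRKCQ, a kinase of T cell signalling, by 4.35 (SE 0.62). HLA-DRB1, a class II antigen-presenting chain, rose from 1.13 ± 0.562 to 33.7 ± 16.2 CPM, and SAMD9L, an interferon-induced gene, from 1.54 ± 0.973 to 38.8 ± 20.3 CPM. A unigene named CXCL13, a chemokine whose identity is uncertain because its NR name is interleukin-8-like, rose from 0.0300 ± 0.0261 to 29.0 ± 34.8 CPM (adjusted p = 0.0373), with 69.2 CPM in HSK 7 against 6.86 in HSK 2. With counts of both SAMD9L unigenes summed, its log2 fold change was 2.27, past no threshold (adjusted p = 0.0638, in a range of 1.29e-14 to 0.194 over all settings). PRKCQ missed the threshold with counts summed per gene name too (adjusted p = 0.0532, in a range of 7.77e-11 to 0.213). IGHE stood at 4497 CPM in HSK 7, 993 in HSK 2 and 912 in HSK 19, and the HSK means of IGLL5, IGHM, IGJ and POU2AF1 also drew most on HSK 7. Only LEC, a lectin gene, was named among the falling unigenes, from 10.9 ± 2.47 to 1.78 ± 0.677 CPM (log2 fold change -2.61, SE 0.37, adjusted p = 0.0418). DESeq2 called all 10 genes of this paragraph, but limma-voom called only IGHM and IGJ, with an adjusted p of 0.585 for CXCL13, 0.357 for POU2AF1, 0.181 for PRKCQ, 0.0926 for SAMD9L, 0.0661 for HLA-DRB1, 0.0581 for IGHE, 0.0563 for LEC and 0.0505 for IGLL5. Over all settings these adjusted p lay between 1.84e-31 and 0.585.

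At an adjusted p under 0.05, 175 unigenes rose and 7 fell in HSK, against 4444 and 2829 at an unadjusted p under 0.05, where 3872 in all would be reached with no effect. Of these 182 unigenes, 100 had a gene name and 46 had no NR match, and of the 7 that fell 5 had no NR match. Over all tested unigenes, the libraries of the populations did not overlap in 14.8%, where chance gives 10%, and the 182, which the test chose on the same libraries, were among these. DESeq2 called 1408 unigenes higher and 332 lower, limma-voom 89 and 2, and edgeR called 992 and 144 with no filter and 79 and 4 with counts summed per gene name. The calls depended on single libraries. Without GZ 42, edgeR called 0 in either direction, with 4281 and 2809 at an unadjusted p under 0.05, and DESeq2 then called 1173 and 276. Without GZ 35 edgeR called 10 and 0, with 4264 and 2522 at an unadjusted p under 0.05, and DESeq2 called 1113 and 235. Leaving out GZ 40 gave 59 and 3, HSK 7 gave 63 and 1, and HSK 2 gave 191 and 12, while without HSK 19 the counts were 157 and 9. With any 1 library left out, all 182 unigenes kept their sign and an unadjusted p under 0.05, and the smallest adjusted p lay between 0.00358 and 0.0630. Their sign could hardly turn, since the populations did not overlap in any of the 182. They were also chosen by their p on the same libraries, so this is no separate support for them. Of the 21 called unigenes named under the fixed rule, 0 kept the adjusted threshold without GZ 35 or GZ 42, 5 without GZ 40, 10 without HSK 7, 15 without HSK 19 and 17 without HSK 2.

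Genes of melanin synthesis and the melanosome did not pass the test in either direction. TYR, the enzyme that starts melanin synthesis, stood at 10.2 ± 3.41 CPM in GZ and 11.3 ± 5.22 CPM in HSK (SD, n = 3; log2 fold change 0.15, SE 0.37, 95% interval -0.71 to 1.01, adjusted p = 0.947). TYRP1, which acts after it, stood at 49.5 ± 8.70 and 52.1 ± 13.2 CPM (log2 fold change 0.07, 95% interval -0.44 to 0.59). PMEL, which forms the fibrils on which melanin is laid down, stood at 334.8 ± 13.5 and 275.3 ± 44.2 CPM (log2 fold change -0.28, 95% interval -0.67 to 0.10, adjusted p = 0.686). The melanosome protein gene MLANA had a log2 fold change of 0.12 (SE 0.20), and the transporter genes OCA2, SLC45A2 and SLC24A5 had -0.30 (SE 0.26), 0.24 (SE 0.29) and 0.26 (SE 0.31). CD63, the most abundant member with PMEL, had 0.35 (SE 0.17). DCT, another enzyme of the pathway, was too scarce to test, with 2 unigenes at 0 and 1 counts over the GZ libraries and 12 and 3 counts over the HSK libraries, the 12 all in HSK 2. Of the 19 measured members of the melanin list, 0 passed in edgeR, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The list had a median log2 fold change of 0.10 and a camera adjusted p of 0.831. Its score per library differed between the populations by 0.05 (two-sided exact permutation p = 0.6, where 3 against 3 allows no p under 0.1).

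In the list of melanocyte specification and signalling, 1 of 18 measured members rose and 17 did not pass. IRF4, a transcription factor of melanocytes and of lymphocytes, rose from 0.183 ± 0.144 to 14.4 ± 12.6 CPM (n = 3; log2 fold change 6.26, SE 0.83, 95% interval 4.37 to 8.16, adjusted p = 0.0353). It stood at 6.74, 29.0 and 7.48 CPM in HSK 2, 7 and 19, in which the B cell gene POU2AF1 stood at 11.53, 57.65 and 10.6. Which cells carried IRF4 was not tested. A second unigene named IRF4, with 223 counts in GZ and 433 in HSK, had a log2 fold change of 0.95 (SE 0.39, adjusted p = 0.498). ASIP, the antagonist of the melanocortin receptor, stood at 4.42 ± 3.13 CPM in GZ and 1.47 ± 1.04 CPM in HSK (log2 fold change -1.57, SE 0.63, 95% interval -3.02 to -0.13, unadjusted p = 0.0363, adjusted p = 0.481). The unigene named MC1R, whose identity is uncertain because its NR name is tubulin beta-3 chain, had a log2 fold change of -0.54 (SE 0.35, adjusted p = 0.715). MITF, the regulator of melanocyte genes, had 0.18 (SE 0.19), KIT -0.06 (SE 0.29), its ligand gene KITLG -0.01 (SE 0.22) and EDNRB -0.27 (SE 0.26). PAX3 stood at 1.32 and 0.629 CPM (log2 fold change -1.07, SE 0.42, adjusted p = 0.463), and SOX10 had -0.08 (SE 0.21). Adjusted over the list alone IRF4 was again the 1 member past the threshold, and over all genes DESeq2 called 1 member higher and limma-voom 0. The list's median was -0.25 and its camera adjusted p 0.325. With counts of both IRF4 unigenes summed the log2 fold change was 2.51, past no threshold (edgeR adjusted p = 0.107). Its adjusted p was 0.135 without GZ 35, 0.128 without GZ 40 0.175 without GZ 42 and 0.390 in limma-voom, in a range of 1.02e-14 to 0.390 over all settings.

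**Figure D1:**
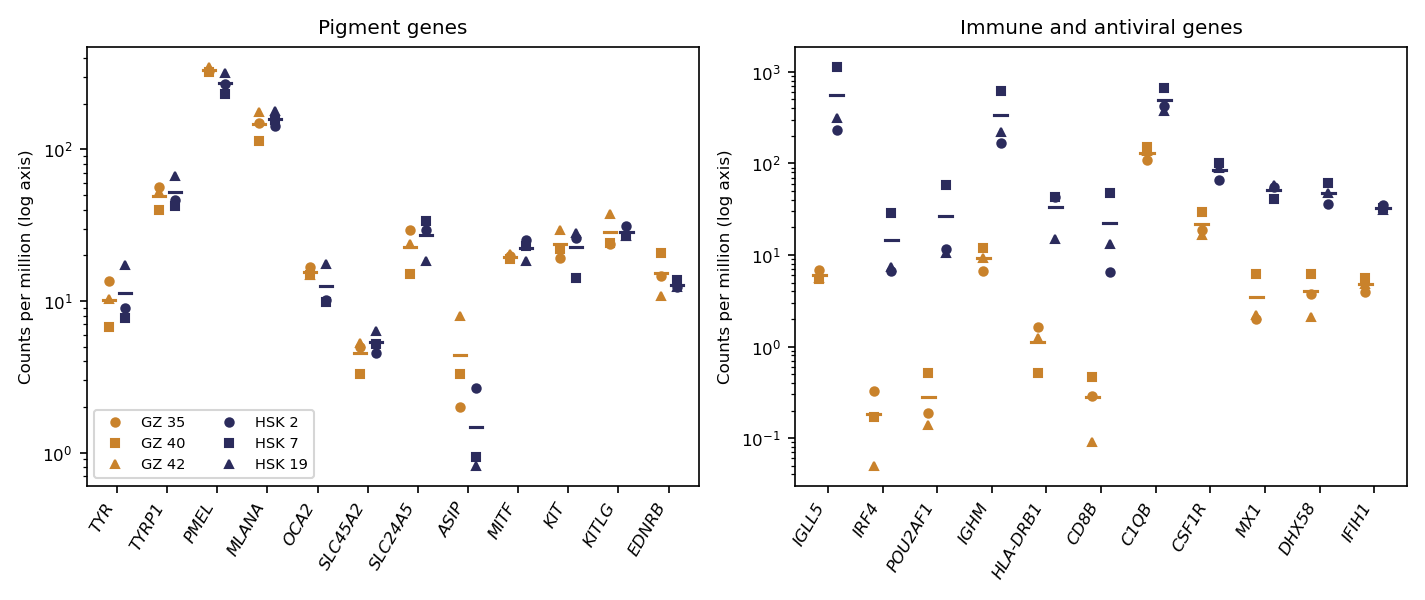
CPM on a log axis in each of the 6 libraries, for 12 pigment genes on the left and 11 immune and antiviral genes on the right, with a bar at each population's mean. IRF4 and CSF1R, the called members of the pigment lists, are drawn on the right, though which cells carried them was not tested. TYR lies at 10.2 and 11.3 CPM in GZ and HSK, and IGLL5 at 5.98 and 560.2 CPM.

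The other pigment lists held 1 unigene called by edgeR. CSF1R, a receptor of xanthophores and of macrophages, rose from 21.6 ± 7.08 to 85.3 ± 18.4 CPM (n = 3; log2 fold change 1.98, SE 0.27, adjusted p = 0.0386). That p was 0.192 without GZ 35, 0.183 without GZ 42, 0.104 without HSK 7 and 0.0676 without HSK 19, in a range of 1.66e-07 to 0.192 over all settings. In the pteridine and xanthophore list 1 of 11 members passed over all genes, and adjusted over the list alone 2 rose and 1 fell, as many as DESeq2 called over all genes, while limma-voom called 1 higher. SPR, an enzyme of pteridine synthesis, had a log2 fold change of 1.37 (SE 0.28, adjusted p = 0.124 over all genes and 0.00643 over the list), and GCH1, which starts that synthesis, had -2.05 (SE 0.62, 0.307 and 0.0364). The list had a camera adjusted p of 0.383. In the list of purine synthesis and iridophores 0 of 16 members passed in edgeR, with 1 higher and 1 lower at an unadjusted p under 0.05, and its camera adjusted p was 0.626. IMPDH2 and PNP had -0.02 (SE 0.27) and -0.46 (SE 0.25), and the list's median of -0.06 and its mean of 0.06 differed in sign, with the test downward. ADSS1, its member with the largest value at 2.74 (SE 1.25), is known as the muscle form of its enzyme, and it stood at 51.4, 10.9 and 0.340 CPM in HSK 2, 7 and 19, in the order of the skeletal muscle genes. In the carotenoid list 0 of 13 members passed, with 2 higher at an unadjusted p under 0.05 and a camera adjusted p of 0.337. PLIN2 and SCARB1 there had 0.25 (SE 0.23) and 0.24 (SE 0.43). In the melanosome transport list 0 of 11 passed, with 1 lower at an unadjusted p under 0.05 and a camera adjusted p of 0.337. With every unigene of a name that list passed downward (camera adjusted p = 0.0460), in a range of 0.0460 to 0.645 over all settings. KIF5B and RAB1A there had -0.13 (SE 0.18) and 0.06 (SE 0.20). Neither DESeq2 nor limma-voom called a member of the purine, carotenoid or transport lists.

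Genes of the interferon and antiviral response were higher in HSK, with all 14 measured members positive. The list had a median log2 fold change of 1.67 and a camera adjusted p of 2.49e-42 at the preset correlation, with an adjusted p = 0.0768 with an estimated correlation and 0.0146 in fry, in a range of 1.36e-56 to 0.0768 over all settings. MX1, an antiviral GTPase gene, rose from 3.46 ± 2.35 to 51.6 ± 9.22 CPM (n = 3; log2 fold change 3.89, SE 0.45, adjusted p = 0.0226). The RNA sensor genes DHX58, DDX58 and IFIH1 rose by 3.58 (SE 0.41), 3.04 (SE 0.25) and 2.75 (SE 0.21), and SAMHD1, an antiviral triphosphohydrolase gene, by 2.14 (SE 0.31). These 5 members passed over all genes in edgeR, where DESeq2 called 10 and limma-voom 4, and 9 did not, such as IRF1, at 1.90 (SE 0.28, adjusted p = 0.0505). All 14 passed when adjusted over the list alone. With a library left out, the adjusted p of IFIH1 was 0.0504 without GZ 35 and 0.0712 without GZ 42, in a range of 8.30e-24 to 0.0712 over all settings. DDX58 also missed the threshold without these libraries, and MX1 and DHX58 missed it without HSK 7 too. The list's score per library was 0.91 to 1.15 in HSK and -1.42 to -0.69 in GZ (exact permutation p = 0.1, the smallest that 3 against 3 allows). Skeletal muscle genes differed between the HSK libraries but not in that order, since HSK 19 had the highest interferon score and the lowest muscle score, 1.15 and -5.22.

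Macrophage and granulocyte genes were higher in HSK, where 7 of 12 measured members rose in edgeR and 5 did not pass, while DESeq2 called 9 higher and limma-voom 5. The median was 1.92 and the camera adjusted p 3.24e-31, with an adjusted p = 0.175 with an estimated correlation and 0.101 in fry, and a range of 5.55e-35 to 0.175 over all settings. Scores per library were 0.66 to 1.32 in HSK and -1.26 to -0.23 in GZ (exact permutation p = 0.1). The complement genes C1QC and C1QB rose from 145.9 ± 32.1 to 665.9 ± 209.8 CPM and from 132 ± 21.0 to 488 ± 154 CPM (n = 3; adjusted p = 0.0271 and 0.0354), the latter a log2 fold change of 1.89 (SE 0.25). CD68, a lysosomal protein gene of macrophages, rose by 1.76 (SE 0.21), and CYBB, a subunit gene of the phagocyte oxidase, by 2.22 (SE 0.29). MPEG1, PTPRC and CSF1R were the others that rose, and LYZ, with a log2 fold change of -0.02 (SE 0.48), was the 1 negative member. Adjusted over the list alone 9 members rose. C1QC had an edgeR adjusted p of 0.137 without GZ 35, 0.0550 without GZ 40, 0.155 without GZ 42 and 0.0513 without HSK 7, in a range of 8.84e-10 to 0.155 over all settings, and CD68 missed the threshold without the same libraries. C1QB missed it without these and HSK 2, and CYBB with any library left out.

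Lymphocyte genes were higher in HSK too, where 2 of 11 measured members rose in edgeR and 9 did not pass, while DESeq2 called 7 higher and limma-voom 1. The median was 2.59 and the camera adjusted p 3.65e-17, with an adjusted p = 0.242 with an estimated correlation and 0.133 in fry, and a range of 1.73e-26 to 0.242 over all settings. Its scores were 0.53, 2.31 and 1.08 in HSK 2, 7 and 19, against -1.33 to -1.28 in GZ (exact permutation p = 0.1). The edgeR calls were JCHAIN, the IGJ unigene already given, and a unigene entered as CD8B, whose identity is uncertain because NR names it a chain of the T cell coreceptor CD8 and Swiss-Prot an immunoglobulin kappa chain. It rose from 0.282 ± 0.188 to 22.4 ± 21.9 CPM (n = 3; log2 fold change 6.27, SE 0.89, adjusted p = 0.0423). Another unigene that NR names a CD8 beta chain was not the one entered, though it was more abundant in HSK. It stood at 11.04, 82.92 and 19.05 CPM in HSK 2, 7 and 19, and edgeR called it higher too (log2 fold change 6.405, adjusted p = 0.0356). CD3E, a surface protein gene of T cells, had a log2 fold change of 0.72 (SE 0.32, adjusted p = 0.546). PRF1, of cytotoxic cells, was the 1 negative member at -2.15 (SE 1.00), with GZ 42 at 52.4 CPM against 2.90 and 3.83 CPM in the other GZ libraries. Adjusted over the list alone 9 members rose. The unigene entered as CD8B had an edgeR adjusted p of 0.211 without GZ 35, 0.124 without GZ 40, 0.204 without GZ 42, 0.0515 without HSK 7 and 0.0534 without HSK 19, and 0.401 in limma-voom, in a range of 7.00e-15 to 0.401 over all settings. JCHAIN missed the threshold without GZ 35, GZ 40 or GZ 42. With any 1 library left out, the interferon, macrophage and lymphocyte lists kept their camera call.

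The inflammation list had 0 of 11 members past the threshold in edgeR, with 3 higher and 1 lower at an unadjusted p under 0.05, 1 called higher by DESeq2 and 0 by limma-voom. TLR4, a receptor for bacterial products, had a log2 fold change of 2.34 (SE 0.37, adjusted p = 0.0614 over all genes and 0.00197 adjusted over the list alone, where it was the 1 member to pass). CFB and CEBPB, the most abundant members, had 1.64 (SE 0.53) and 0.07 (SE 0.20). The list's median of -0.10 and its mean of 0.21 differed in sign, with the test upward (camera adjusted p = 0.562), and without GZ 40 the adjusted p was 0.0370, in a range of 0.0370 to 0.863 over all settings.

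Among annotation terms, MHC class II protein complex had 6 of its 24 tested unigenes among the 103 rising unigenes with a term (one-sided Fisher's exact test, 69.7-fold enrichment, edgeR calls, adjusted p = 2.82e-07). Its members CD74, the chaperone of class II molecules, and HLA-DRA rose from 23.8 to 368.9 CPM and from 20.6 to 236.7 CPM, by 3.96 (SE 0.24) and 3.53 (SE 0.38) on the log2 scale. The same 6 unigenes were behind the term antigen processing and presentation, 6 of 33 (adjusted p = 1.13e-06). Immune response had 10 of 229 (12.2-fold, adjusted p = 4.23e-06), and the same 6 unigenes were among these 10, so the 3 terms are not separate results. Reads of near-identical class II copies could be split between unigenes, so the 6 are not separate genes for certain. For falling unigenes, 0 terms passed with 1 annotated unigene, and 4 terms had an unadjusted p under 0.05. Without GZ 42, where edgeR called 0 unigenes, 0 terms passed. With all 6 libraries, DESeq2 calls gave 11 terms and camera on each term 14.

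**Figure D2:**
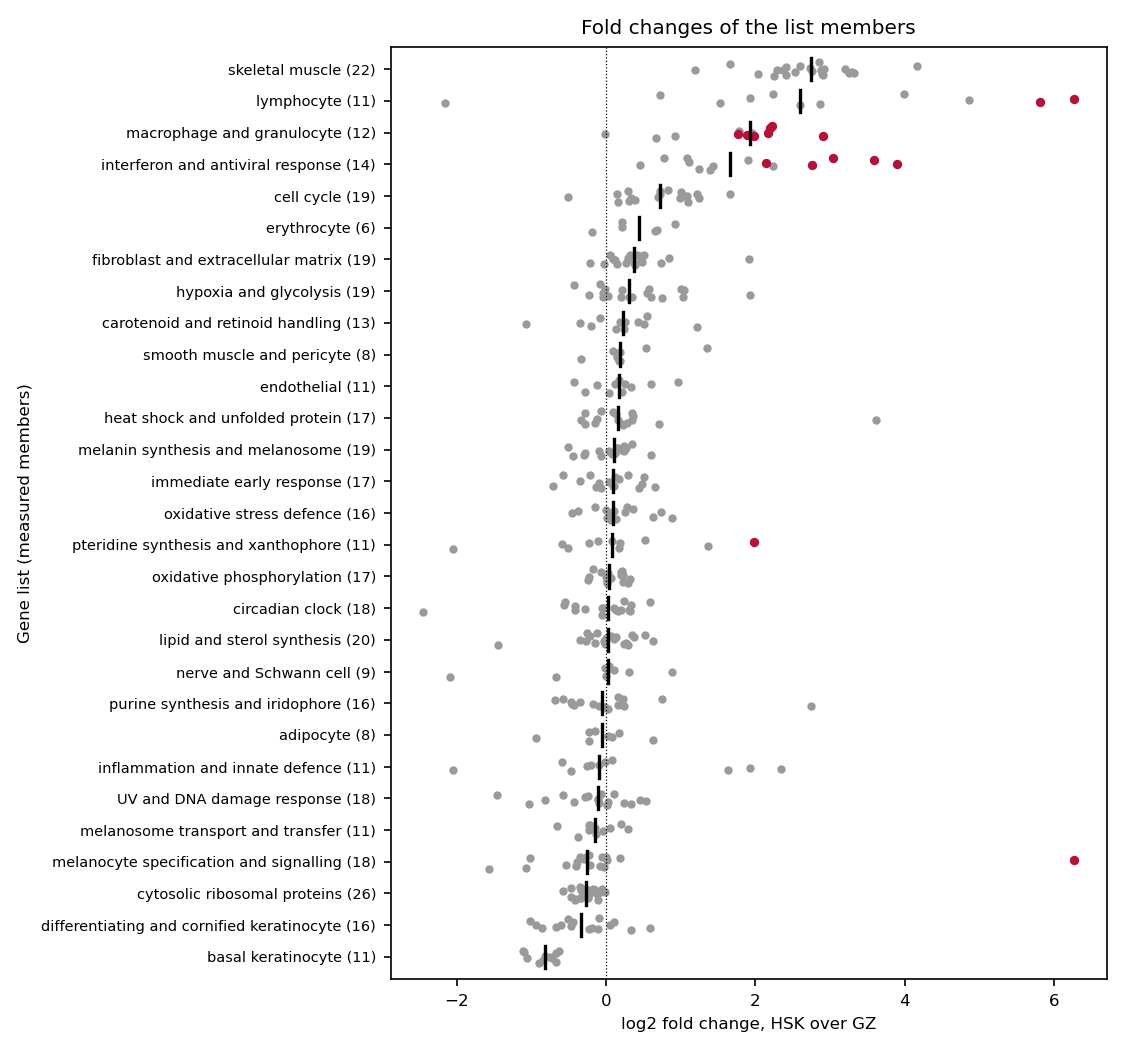
Log2 fold change (HSK over GZ) of each measured member of the 29 gene lists, red where the adjusted p was under 0.05 and grey elsewhere, with a black bar at each list's median and the number of measured members in brackets. The interferon, macrophage and lymphocyte medians lie at 1.67, 1.92 and 2.59, and the melanin synthesis median at 0.10.

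Basal keratinocyte genes were lower in HSK as a list, with all 11 measured members negative and a median of -0.82. The camera adjusted p was 3.91e-10, kept with any library left out, with an adjusted p = 0.323 with an estimated correlation and 0.155 in fry, and a range of 3.10e-14 to 0.323 over all settings. The list's scores overlapped, at -0.02 in GZ 40 and -0.01 in HSK 2 (exact permutation p = 0.2). KRT15 and KRT5, keratins of the basal layer of the epidermis, had log2 fold changes of -0.67 (SE 0.34) and -0.75 (SE 0.30). KRT14 stood at 252 ± 62.2 CPM in GZ and 116 ± 36.8 CPM in HSK (n = 3; log2 fold change -1.12, SE 0.29), and COL17A1, which anchors basal cells, at 692 ± 232 and 324 ± 118 CPM (log2 fold change -1.09, SE 0.33). None passed over all genes in edgeR (0 of 11), but 10 fell when adjusted over the list alone, 10 had an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0. Differentiating and cornified keratinocyte genes fell as a list as well, with 12 of 16 members negative, 0 past the threshold in edgeR, DESeq2, limma-voom or over the list alone, and 1 higher and 4 lower at an unadjusted p under 0.05. That list's median was -0.33 and its camera adjusted p 0.0163, with an adjusted p = 0.288 with an estimated correlation, 0.118 in fry, 0.108 without GZ 35, 0.0548 without HSK 2 and a range of 0.00308 to 0.288 over all settings. The scores were -0.20 to -0.07 in HSK and 0.02 to 0.28 in GZ (exact permutation p = 0.1). KRT10 and DSP there had -0.94 (SE 0.32) and -0.44 (SE 0.27), and TGM1, a crosslinking enzyme gene, had 0.59 (SE 0.19).

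Fibroblast and matrix genes rose as a list, with 17 of 19 members positive and a median of 0.38. The camera adjusted p was 0.00688, with an adjusted p = 0.803 with an estimated correlation, 0.603 in fry, 0.0685 without GZ 35, 0.293 without GZ 40, 0.323 without HSK 2 and a range of 5.24e-06 to 0.803 over all settings. The list's scores overlapped, since GZ 42, at 0.26, lay above HSK 19, at 0.18, and HSK 7, at -0.24 (exact permutation p = 0.4). COL3A1 and DCN, collagen and proteoglycan genes of the dermis, had log2 fold changes of 0.51 (SE 0.42) and 0.31 (SE 0.25). None passed over all genes in edgeR (0 of 19, with 2 higher at an unadjusted p under 0.05, 1 called higher by DESeq2 and 0 by limma-voom). Adjusted over the list alone, BGN rose, from 8.54 ± 0.901 to 32.1 ± 20.8 CPM (n = 3; log2 fold change 1.91, SE 0.41).

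Skeletal muscle genes differed most within HSK. CKM, the muscle creatine kinase gene, stood at 2941 CPM in HSK 2, 1654 in HSK 7 and 0.910 in HSK 19, against 115 to 456 CPM in GZ. ENO3, a muscle enolase gene, had a log2 fold change of 2.54 (SE 1.59) and CKM one of 2.41 (SE 1.59). All 22 measured members had a positive log2 fold change, with a median of 2.74. The camera adjusted p was 0.00443, with an adjusted p = 0.851 with an estimated correlation, 0.711 in fry and a range of 6.64e-53 to 0.851 over all settings. It was 0.0777 without GZ 40, 0.0593 without GZ 42 and 0.0682 without HSK 7, and without HSK 2 the direction turned (0.727, downward). In edgeR, DESeq2, limma-voom and adjusted over the list alone 0 members passed, with 4 higher at an unadjusted p under 0.05. The score per library ran from -5.22 in HSK 19 to 3.86 in HSK 2, and from -0.81 to 0.73 in GZ (exact permutation p = 0.9).

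The hypoxia and glycolysis list, which shares glycolytic enzymes with muscle, rose with 13 of 19 members positive, a median of 0.31 and a camera adjusted p of 0.0373. The call was lost, with an adjusted p = 0.313 with an estimated correlation, 0.133 in fry, 0.0967 without GZ 40, 0.0593 without GZ 42, 0.145 without HSK 2, 0.0595 without HSK 7, 0.0606 with at least 1 CPM in 3 libraries, 0.180 with counts summed per gene name and a range of 3.39e-04 to 0.313 over all settings. In HSK 2, 7 and 19 its scores were 0.43, 0.25 and -0.04, against -0.34 to -0.13 in GZ (exact permutation p = 0.1). GAPDH and ALDOA, enzymes of glycolysis, had log2 fold changes of 1.00 (SE 0.43) and 1.93 (SE 0.82), and ALDOA stood at 1953, 920 and 97.3 CPM in HSK 2, 7 and 19, the order of the muscle genes. None passed in edgeR, DESeq2, limma-voom or over the list alone (0 of 19), with 5 higher at an unadjusted p under 0.05. In the heat shock list 0 of 17 passed in any of the tools (1 higher at an unadjusted p under 0.05, camera adjusted p = 0.562). HSP90AB1 and HSPA8 there had -0.29 (SE 0.18) and 0.15 (SE 0.25), and HSPB1, abundant in muscle, had 3.62 (SE 1.65), with 825 CPM in HSK 2 and 0.290 in HSK 19.

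**Figure D3:**
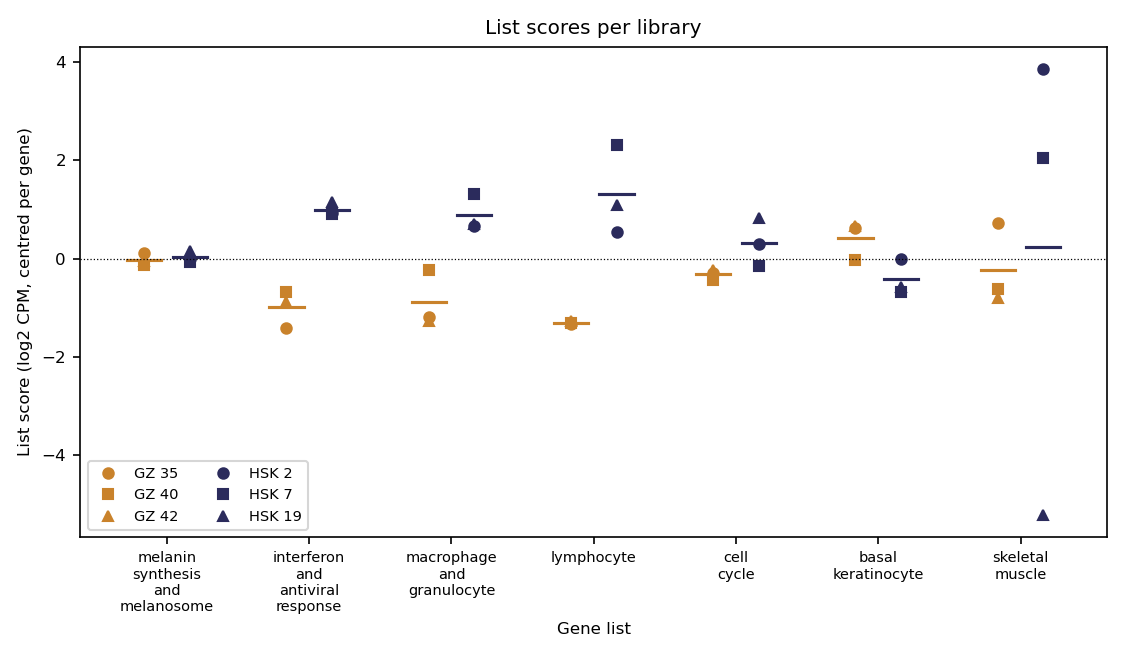
Score of 7 gene lists in each of the 6 libraries, where a score is the mean over members of the log2 CPM centred per gene, with a bar at each population's mean. Interferon scores lie between 0.91 and 1.15 in HSK and between -1.42 and -0.69 in GZ, while the skeletal muscle score spans -5.22 to 3.86 within HSK.

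Cell cycle genes rose as a list, with 18 of 19 members positive and a median of 0.71. The camera adjusted p was 1.94e-04, kept with any library left out, with an adjusted p = 0.450 with an estimated correlation, 0.255 in fry and a range of 2.54e-08 to 0.450 over all settings. By library, the scores in HSK 2, 7 and 19 were 0.29, -0.15 and 0.82, so HSK 7 lay close to GZ, at -0.44 to -0.23 (exact permutation p = 0.1). PCNA and RRM2, genes of DNA replication and the most abundant members, had log2 fold changes of 0.33 (SE 0.34) and -0.51 (SE 0.46), while KIF11, a motor gene of the mitotic spindle, had 1.66 (SE 0.44, adjusted p = 0.230). In edgeR and over the list alone 0 passed, with 7 higher at an unadjusted p under 0.05, 1 called higher by DESeq2 and 0 by limma-voom. Cytosolic ribosomal protein genes fell as a list, with all 26 members negative and a median of -0.27. The camera adjusted p was 0.00133, with an adjusted p = 0.709 with an estimated correlation, 0.273 in fry, 0.117 without GZ 42, 0.0838 without HSK 2, 0.543 with every unigene of a name and a range of 9.38e-05 to 0.709 over all settings. The list's scores overlapped, at -0.04 in GZ 40 and 0.03 in HSK 7 (exact permutation p = 0.2). RPS14 and RPS6 had -0.32 (SE 0.22) and -0.31 (SE 0.18), and 0 members passed in edgeR, DESeq2, limma-voom or over the list alone, with 3 lower at an unadjusted p under 0.05.

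In the UV and DNA damage list, DDB2, a sensor of UV damage, stood at 32.6 ± 1.88 CPM in GZ and 16.0 ± 1.97 CPM in HSK (n = 3; log2 fold change -1.03, SE 0.18, adjusted p = 0.0721 over all genes). Adjusted over the list alone 2 members fell, DDB2 among them (0.00553). Over all genes 0 of 18 passed in edgeR and 0 in limma-voom, while DESeq2 called 2 lower, with 1 higher and 3 lower at an unadjusted p under 0.05. DDB1 and GADD45A, the most abundant, had -0.07 (SE 0.16) and -0.10 (SE 0.18), and the camera adjusted p was 0.116. It was 0.0281 with counts summed per gene name and 0.0460 with every unigene of a name, in a range of 0.0281 to 0.393 over all settings.

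The remaining lists had 0 called members in edgeR, DESeq2, limma-voom and over the list alone, and did not pass in camera. Among skin cell types, smooth muscle and pericyte genes had a median of 0.18 (8 members, adjusted p = 0.430), with MYH11 and MYLK at 0.17 (SE 0.14) and 0.19 (SE 0.15). Endothelial genes had a median of 0.18 (11 members, 2 higher at an unadjusted p under 0.05, adjusted p = 0.337, and 0.0248 without GZ 40 in a range of 0.0248 to 0.917 over all settings), with VWF and CDH5 at -0.43 (SE 0.25) and 0.33 (SE 0.21). Nerve and Schwann cell genes had a median of 0.02 and a mean of -0.16, with the test downward (9 members, 2 lower at an unadjusted p under 0.05, adjusted p = 0.798), and MBP, a myelin gene, stood at 0.04 (SE 0.17). Adipocyte genes had a median of -0.06 (8 members, adjusted p = 0.997), with LPL and LIPE at -0.23 (SE 0.43) and 0.17 (SE 0.36). Erythrocyte genes had a median of 0.44 (6 members, adjusted p = 0.229, with 0.00139 without HSK 7 and 0.0460 with every unigene of a name, in a range of 0.00139 to 0.851 over all settings), with TFRC and SLC4A1 at -0.19 (SE 0.24) and 0.21 (SE 0.33). The hemoglobin unigene HBB1, chosen after its values were seen, stood at 1553 ± 320.5 CPM in GZ and 3195 ± 1992 CPM in HSK (n = 3; log2 fold change 1.04, SE 0.40, adjusted p = 0.462), with 5455 CPM in HSK 19 and 1691 in HSK 7.

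Among stress and metabolic lists, immediate early genes had a median of 0.09 (17 members, 1 higher and 1 lower at an unadjusted p under 0.05, adjusted p = 0.831), with JUN and IER2 at -0.06 (SE 0.19) and 0.30 (SE 0.17). Oxidative stress genes had a median of 0.09 (16 members, 1 higher at an unadjusted p under 0.05, adjusted p = 0.337), with GPX1 and NQO1 at 0.26 (SE 0.17) and 0.06 (SE 0.16). Circadian genes had a median of 0.03 and a mean of -0.14, with the test downward (18 members, 1 lower at an unadjusted p under 0.05, adjusted p = 0.562), and BHLHE40 and NFIL3 stood at 0.11 (SE 0.16) and -0.05 (SE 0.20). Genes of oxidative phosphorylation had a median of 0.04 (17 members, adjusted p = 0.699), with ATP5F1B and CYC1 at 0.06 (SE 0.18) and 0.04 (SE 0.17). Lipid and sterol genes had a median of 0.03 (20 members, 1 higher at an unadjusted p under 0.05, adjusted p = 0.831), with ELOVL4 and FADS1 at 0.11 (SE 0.34) and -0.26 (SE 0.25). In all, 10 of the 29 lists passed in camera at the preset correlation, 7 upward and 3 downward, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.0768. At the preset correlation, splits of the libraries that mixed the populations passed 3 to 9 lists each. A camera call there thus does not by itself show a difference between the populations. By fry 1 list passed, that of the interferon response.

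In the table of GZ against HSK that the authors deposited, 1297 unigenes had an adjusted p under 0.05, 1113 with the higher mean in HSK and 184 in GZ. Of these, 1046 and 156 were tested with edgeR here, and all 175 risen and 7 fallen unigenes were among them, with 0 in opposite directions. Over all tested unigenes the sign was the same in 99.0%. In the authors' values IGLL5 had a log2 fold change of 6.57, HSK over GZ (adjusted p = 2.17e-34), and LEC had -2.61 (adjusted p = 9.30e-08). TYR had 0.14, PMEL -0.28 and ASIP -1.58, with adjusted p = 1, 1 and 0.599. Their calls included 9 macrophage, 6 lymphocyte and 9 interferon list members higher in HSK, and 0 of the 19 members of the melanin list.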

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

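The fit with the skeletal muscle score as a covariate and DESeq2 without single libraries were chosen after seeing the data, and the other settings before the data were examined. No paired analysis was possible because the individual numbers differ between the populations. With DESeq2 size factors or upper-quartile scaling in edgeR, with at least 1 CPM in 3 libraries, with an absolute log2 fold change above 1 and with the muscle covariate, the counts of risen and fallen unigenes stayed within 1.5 times 175 and 7, at 137 to 176 and 7 to 9, and the counts of lists and terms, where recomputed, stayed at 9 or 10 and at 3 or 4. Upper-quartile scaling moved the median log2 fold change by -0.08. The cause was not tested for the changes that follow, except where the setting's own construction shows it. With no filter, which tests 250361 unigenes in place of 77439, edgeR called 992 risen and 144 fallen unigenes and 10 terms, and all 182 were among them. DESeq2 called 1408 and 332, with 11 terms and all 182 among them, limma-voom 89 and 2, 89 of them shared, and counts summed per gene name, which drop unigenes with no name, 79 and 4. With camera on each term 14 terms passed. With an estimated correlation 0 of the 29 lists passed in camera, with adjusted p = 0.323 for basal keratinocytes, 0.175 for macrophages, 0.242 for lymphocytes and 0.0768 for interferon, against 10 at the preset value. By fry 1 list passed, with 0.155, 0.101 and 0.133 for the former lists in that order. Leaving out each library in turn gave 0 to 191 risen and 0 to 12 fallen unigenes in edgeR, 5 to 10 lists and 0 to 4 terms. The extremes of the unigene counts came without GZ 42 (0 and 0, with 4281 and 2809 at an unadjusted p under 0.05, 7 lists and 0 terms) and without HSK 2 (191 and 12, 5 lists), while the other values were 10 and 0 without GZ 35, with 4264 and 2522 at an unadjusted p under 0.05, 59 and 3 without GZ 40, 63 and 1 without HSK 7 and 157 and 9 without HSK 19. The most lists, 10, passed without HSK 19, and the most terms, 4, without HSK 7. DESeq2 with GZ 35 left out called 1113 and 235, and with GZ 42 left out 1173 and 276. The skeletal muscle list turned downward with the muscle covariate, which is built from its own members (adjusted p = 0.845), and without HSK 2 (0.727), in a range of 6.64e-53 to 0.727 over libraries left out. The interferon, macrophage, lymphocyte, basal keratinocyte and cell cycle lists kept their direction and camera call in each of these 6 fits. All 21 called unigenes named under the fixed rule kept their sign wherever they had a value, and 11 stayed past the threshold in limma-voom, 16 of 19 with summed counts, 16 with the covariate and 18 with upper-quartile scaling. With a library left out that sign could hardly turn, since the populations did not overlap in these unigenes. At this depth and with 3 libraries per population, simulated changes of 1 on the log2 scale were recovered in 2.99% and of 3 in 77.3% of unigenes.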

Other observations

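Beyond the lists, further called unigenes, chosen after their values were seen, carried names of antiviral and antigen-presenting proteins. CD74, the chaperone of class II molecules, had an edgeR adjusted p of 0.00670 and a log2 fold change of 3.96. DDX60, USP18 and XAF1, which interferon induces in vertebrates, rose by 3.98, 3.17 and 3.48, and 3 unigenes named ZNFX1 rose by 2.49 to 2.68. CIITA, the regulator of class II genes, rose by 2.53, B2M, the light chain of class I molecules, by 2.50, and TLR7, a sensor of single-stranded RNA, by 2.82. SIGLEC1 and VSIG4, surface genes of macrophages, rose by 3.11 and 2.52. When camera was run on each annotation term, 14 terms passed, all upward, and those outside antigen presentation and immune response included chemokine activity (24 unigenes, adjusted p = 2.50e-04) and cellular iron ion homeostasis (19 unigenes, adjusted p = 0.0151). By count, 10 unigenes were at 0 in every GZ library with at least 10 counts in every HSK library, 3 of them with immunoglobulin names in NR, and 4 unigenes showed the converse.

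All tests of explanations in this part were chosen after the results were seen. The immune and antiviral genes higher in HSK were tested first. Blood in the HSK samples was tested with the 4 most abundant hemoglobin unigenes, whose highest log2 fold change was 1.20 (SE 0.41). That value's interval, 0.27 to 2.13, included 1.67, the lowest median of the 3 immune lists, so it does not decide on blood. This unigene stood at 1114.57, 690.78 and 2338.56 CPM in HSK 2, 7 and 19, against 470.05 to 691.15 in GZ. HSK 7 had interferon, macrophage and lymphocyte scores of 0.91, 1.32 and 2.31, above every GZ library. More red blood cells thus do not account for these scores in HSK 7. Hemoglobin does not measure white blood cells, so blood richer in them was not tested. Muscle taken with the skin was tested with the muscle score as a covariate, where the 37 immune members kept a median of 1.93 (SD 1.53) against 1.96. That score is built from the same libraries, and 11 of their unigenes were then called against 14. Its means were -0.23 in GZ and 0.23 in HSK (SD 4.80 in HSK), so the covariate could hardly move the population difference and decides nothing. HSK 19, with the lowest muscle score at -5.22, had interferon, macrophage and lymphocyte scores of 1.15, 0.71 and 1.08. These lay above every GZ library, so muscle does not account for them in HSK 19. Reads moving between unigenes of 1 gene were tested with counts summed per gene name. The median of the 34 list members with a gene name was then 1.89 (SD 1.41), against 1.94. Summing can change little where a name has 1 tested unigene, as for MX1, IFIH1, CD68, C1QB, C1QC and CYBB, while DDX58 and DHX58 had 4 and 3. That median thus does not decide on moving reads. Single genes are not covered by it, nor are unigenes with no gene name, such as some class II and immunoglobulin ones. Summing took the log2 fold change of IRF4 from 6.26 to 2.51 and that of SAMD9L from 4.65 to 2.27. Population, place, season and infection are not separated by the design, so a higher immune content of HSK skin as a trait of the population may hold or not, and was not tested.

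Skeletal muscle genes were uneven between the HSK individuals. In 22 of the 22 members HSK 19 was lowest and HSK 2 highest. Uneven amounts of muscle in the skin pieces would give that order, but so would a coordinated difference of biology between the individuals, and with an estimated correlation of 0.974 between members the order was fixed by the pattern itself, so these could not be told apart. A failed library HSK 19 would lose abundant transcripts of every kind. Among unigenes at 10 CPM or more in each of the other libraries, HSK 19 lay below 10% of the lowest of these in 7 of 13 muscle list members but in 4 of 11796 other unigenes, or 0.0339% (exact binomial upper 95% limit 0.0868%, for counting error only), which argues against it.

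Basal keratinocyte genes were lower in HSK as a list (median -0.82, camera adjusted p = 3.91e-10, in a range of 3.10e-14 to 0.323 over all settings), but 0 of 11 members passed in edgeR over all genes, with 10 lower at an unadjusted p under 0.05, 1 called lower by DESeq2 and 0 by limma-voom, and the call was lost with an estimated correlation (adjusted p = 0.323) and in fry (0.155), so the difference is itself uncertain. Dilution by RNA from outside the resident cells would lower the markers of other resident cells alike. The 47 members of the endothelial, nerve, smooth muscle and melanin lists had a pooled median of 0.12 (SD 0.49), which argues against that form. More RNA of the dermis, with its vessels and nerves, would not lower these markers, and the fibroblast list had a median of 0.38. Dilution of the epidermis by dermis is thus not decided by these lists. A smaller share of epidermis could not be told apart from a change in basal cells alone. The differentiating keratinocyte list had a median of -0.33 (SD 0.46), more than its SD above the basal median, but its most abundant member, KRT10, was at -0.94 (SE 0.32), which keeps it open. A difference between the populations in the basal layer stays open and was not tested.

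The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10, the real one, the counts were as large as 175 risen and 7 fallen unigenes, 10 lists and 3 terms, and the highest of the other splits were 1 unigene in the larger direction, 9 lists and 0 terms. Every other split passed at least 3 lists, so the count of lists sets the real split little apart. The unadjusted camera p of the interferon list was 8.57e-44 in the real split and 3.36e-05 at the lowest in the others.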
